A study of Mus musculus with 6 samples.

How the data were processed

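The data were 6 Affymetrix arrays made from total RNA of whole MC3T3-E1 cells, with biotin as the label. Of the samples 3 were treated with DMSO and 3 with NU7441, and groups and replicate numbers were taken from the labels. The deposited table holds 1 log2 value per probe set and array. That the values are log2 was read from their range, and the background correction, summarisation and normalization behind them are not given in the sources used here. Per the labels' protocols, RNA was purified on columns and prepared to the array maker's specifications. The arrays' medians differed by little, so the deposited log2 values were used with no further normalization, and 0 columns of other samples were present.

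The table had 41345 probe sets. The platform annotation gave 1 gene symbol for 23521, several for 1814 and none here for 16010, and only those with 1 symbol were named. The Entrez number of 23328 of them was in the reference gene table and that of 193 was not, and 0 symbols changed through it. For the 1082 genes with more than 1 such probe set, the one with the highest mean over the 6 arrays was kept, which left 22180 genes. No filter on level was applied. The 17824 probe sets without a single symbol were tested apart, where limma called 0 at an adjusted p under 0.05 and 1012, or 5.68%, had an unadjusted p under 0.05.

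Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A size of 2-fold was a log2 difference of at least 1. Values are given as log2 differences, NU7441 minus DMSO, with the moderated standard error. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 26 lists. Camera with the correlation estimated per list, and fry, were alternatives. At the estimated correlation 0 of the 10 lists called at the preset one held and 3 lists had an unadjusted p under 0.05, and fry called 0 lists in its test of a shared direction and 4 in its test of change in either direction. The estimated correlation of the inflammatory and NF-kB list, -0.008, was below the preset 0.01, yet its camera p went from 2.01e-06 to 0.00620. Loss of a call at the estimated correlation therefore does not measure correlation between genes alone.

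The comparison, the lists, the alternatives and the rule for named genes were set before the data were examined. The lists were osteoblast differentiation and mineralisation, osteocyte, collagen and matrix assembly, matrix proteases and inhibitors, adipocyte, chondrocyte, smooth muscle and myofibroblast, skeletal muscle, macrophage and endothelial, AP-1 and immediate early, p53 targets, cell cycle, non-homologous end joining, homologous recombination and damage signalling, sterol biosynthesis, amino acid and ATF4 response, unfolded protein response, interferon response, inflammatory and NF-kB, Wnt signalling, BMP and TGF-beta signalling, hypoxia and glycolysis, xenobiotic and oxidative stress, lysosome and autophagy, mitochondrial oxidative phosphorylation, and cytosolic ribosomal proteins. No gene stood on more than 1 of them. Members with no single-symbol probe set were not analysed here, among them the osteoblast genes Runx2, Bglap2, Bglap3 and Spp1.

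The rule named the genes past the threshold with the largest differences, or, where fewer than 5 passed in a direction, the 5 with the smallest p in it, given as not passing. It also named single genes of the study's question, whatever their result, up to 4 members of each list with the smallest p, and genes that hold a stated extreme. Predicted genes and symbols of small RNAs, immunoglobulin and olfactory receptor genes were passed over. Other members given as passing adjusted over a list alone were named after their values were seen.

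Because both groups carry the numbers 1 to 3, it was checked whether same-numbered samples deviate together from their group means. Over genes, the correlation of these deviations was between 0.149 and 0.339 for the same number and between -0.25 and 0.09 for different numbers, and 6 of 6 arrays were closest to their own number. The deviations of a group sum to 0, so these 6 results are not independent of each other. NU7441 1 correlated at 0.149 with DMSO 1 and at 0.09 with DMSO 2, so numbers 1 and 2 were less clearly told apart than number 3. By the rule set beforehand, a correlation over 0.1 in every pair, the numbers were taken to pair the samples. This pairing comes from the data, and no label states it. The test without pairs stayed the reported one, and the replicate number as a block was an alternative. Standard errors are from the test without pairs unless stated.

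The other alternatives were an intensity trend with a robust prior, quantile normalization, median centring, filters on dim genes, the mean of a gene's probe sets, all probe sets, array weights and leaving out each array in turn. Combinations of pairs with other settings, and leaving out both arrays at the ends of the first principal component, were added after the data were examined.

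The tests were tried on simulated data made from the genes' means and their variances shrunk towards a common value. Genes were drawn independently of each other, with 200 of 22180 changed in each of 5 draws. The test without pairs recovered 53.1% of genes changed by 1.41-fold and 97.6% of those changed by 2-fold, and 1.77% of its calls were false. With the replicate block the shares were 74.6% and 99.4%, with 6.26% of calls false, and with the block, the trend and the robust prior 83.3% and 99.4%, with 6.83% false. The test without pairs made 169.8 calls per draw. With fewer changed genes the adjusted threshold is stricter, so these shares do not carry over to real data with 0 calls. In the real arrays Ch25h, at -1.18, had an adjusted p of 0.598 in limma without pairs. With genes drawn independently, camera called a simulated list of 25 genes shifted by -0.25 and 0 of the other 25 lists. In the real lists the estimated correlation ran from -0.043, for skeletal muscle, to 0.897, for cell cycle. The simulation therefore cannot tell how often camera calls unchanged lists of correlated genes. On the real arrays, the other splits of the 6 arrays into 3 and 3 gave between 3 and 11 called lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.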

Results

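Gene expression was measured on 6 Affymetrix arrays of MC3T3-E1 cells, a line of pre-osteoblasts from mouse calvaria that forms mineralising osteoblasts in culture. Confluent cells were kept for 14 days in medium with 50 µg/ml ascorbic acid and 10 mM β-glycerophosphate, which drives osteoblast differentiation. NU7441, an inhibitor of the DNA-dependent protein kinase catalytic subunit, was present at 1 µM in 3 samples, and 3 samples received its solvent, DMSO. Replicate numbers 1 to 3 occur in both groups. Array medians lay between 6.38 and 6.42 on the log2 scale, and the correlation between any pair of arrays lay between 0.989 and 0.993. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

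The comparison of NU7441 with DMSO asks how blocking this kinase alters the transcripts of differentiating osteoblasts, the series being about the phosphorylation of alphaNAC by the kinase. The transcript of alphaNAC, Naca, was at 12.01 ± 0.05 in DMSO and 12.03 ± 0.04 in NU7441 (log2, SD, n = 3 each), a difference of 0.02 (SE 0.06). Prkdc, which encodes the inhibited kinase, differed by 0.04 (SE 0.06), and Btf3, the partner of alphaNAC in its complex, by 0.11 (SE 0.06). Jun, a subunit of the transcription factor AP-1, differed by -0.45 (SE 0.09), while Fos differed by -0.03 (SE 0.17). Ptgs2, the inducible cyclooxygenase, differed by -0.83 (SE 0.29), Lrp6, a Wnt co-receptor, by 0.08 (SE 0.07) and Btf3l4 by 0.06 (SE 0.08). None of these genes passed the test, the adjusted p from limma being 0.598 for Jun, 0.699 for Ptgs2 and 0.963 for Naca. With same-numbered samples as pairs, an intensity trend and a robust prior, a setting added after the data were examined, Jun was lower at an adjusted p of 0.0291 in limma. The signs of the small Naca and Fos differences turned when DMSO 3 or NU7441 2 was left out.

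Over 22180 genes, limma called 0 at an adjusted p under 0.05, the smallest adjusted p being 0.598, and therefore 0 at a size of 2-fold. At an unadjusted p under 0.05 there were 1506 genes, or 6.79%, where chance alone gives 1109 if the arrays are independent. Of these, 775 were higher and 731 lower with NU7441, and centring each array on its median gave 560 and 908. The smallest p belonged to Gm2035, which was passed over below with other predicted genes. Of the remaining genes higher with NU7441, the smallest p was that of Oas1g, of the oligoadenylate synthetase family, with a log2 difference of 1.02 (SE 0.13). Oas1g was at 3.08 ± 0.07 in DMSO and 4.10 ± 0.25 in NU7441 (n = 3 each), below the lower quartile of every array, 5.11 to 5.16, and its signal over background was not analysed here, so the size of this difference is uncertain. Fgfr3, a fibroblast growth factor receptor of the skeleton, followed with 0.46 (SE 0.07), then Adtrp with 0.44 (SE 0.07), Ehd3 with 0.39 (SE 0.06) and Adgrf5 with 0.50 (SE 0.09). Among genes lower with NU7441, Tnfrsf12a, the receptor of the cytokine TWEAK, differed by -0.53 (SE 0.07) and Ddah1 by -0.55 (SE 0.08). Ch25h, which makes 25-hydroxycholesterol, differed by -1.18 (SE 0.18), Grem1, a secreted BMP antagonist, by -0.57 (SE 0.09) and Clic5 by -0.71 (SE 0.11). From Oas1g to Clic5, all 10 had an adjusted p of 0.598 in limma, and in each of them the 3 values of one group lay apart from the 3 of the other. Such separation was found in 1360 genes above and 1472 below, 12.8% of all genes where chance gives 10% if the arrays are independent. Since same-numbered samples deviated together, 1109 and 10% are only rough guides.

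The 95% interval of the difference, from the fit without pairs, excluded a 2-fold change in array signal for 99.2% of genes. That share includes dim genes, since no filter on level was applied. Signal over background was not analysed here, so for dim genes the interval may not bound the change in transcript. With same-numbered samples taken as pairs, limma again called 0 genes, the smallest adjusted p being 0.229, with 2078 genes at an unadjusted p under 0.05. Pairs combined with an intensity trend of the variance called 100 genes, 7 of them by at least 2-fold, a setting added after the data were examined, and no setting fixed in advance called any gene. Of the 10 genes given from Oas1g to Clic5, all but Adtrp were among the 100.

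Genes of osteoblast differentiation and mineralisation were called higher with NU7441 by camera: 20 of 24 measured members were higher and 4 lower, with a median log2 difference of 0.08 and a mean of 0.26 (camera adjusted p = 0.0126). The adjusted p was 0.558 with an estimated correlation. Bglap, which encodes osteocalcin, was at 7.02 ± 0.59 in DMSO and 7.66 ± 0.46 in NU7441, a difference of 0.64 (SE 0.33, n = 3 each). Sp7, the transcription factor osterix, differed by 0.53 (SE 0.24), Alpl, the alkaline phosphatase of mineralising cells, by 0.54 (SE 0.21), and Ibsp, bone sialoprotein, by 0.52 (SE 0.37). Pth1r, the parathyroid hormone receptor, differed by 0.81 (SE 0.36), the phosphate transporter Slc20a1 by -0.34 (SE 0.15) and the collagen gene Col1a1 by 0.04 (SE 0.06). Col1a1 was at 13.47 in DMSO and 13.52 in NU7441, near the arrays' maxima of 13.94 to 13.96, where a rise may not show. No member passed over all genes, and 0 passed adjusted over the list alone in limma, with 1 member, Alpl, at an unadjusted p under 0.05. With same-numbered samples as pairs, 10 members passed adjusted over the list alone, all higher: Sp7, Alpl, Bglap, Ibsp, Dlx5, Dlx3, Pth1r, Ifitm5, Smpd3 and Mef2c. The SE with pairs was 0.14 for Bglap, 0.08 for Sp7, 0.06 for Alpl, 0.07 for Ibsp and 0.06 for Pth1r. For Slc20a1 it was 0.11 and for Col1a1 0.06. The camera call was lost without DMSO 1 (adjusted p = 0.135), without DMSO 2 (0.0816), without NU7441 3 (0.154) and with array weights (0.0539). Leaving out 1 array moved the list's median to between 0.06, without NU7441 3, and 0.18, without NU7441 2, with 0.17 without NU7441 1, 0.15 without DMSO 3 and 0.14 without DMSO 2.

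**Figure D1:**
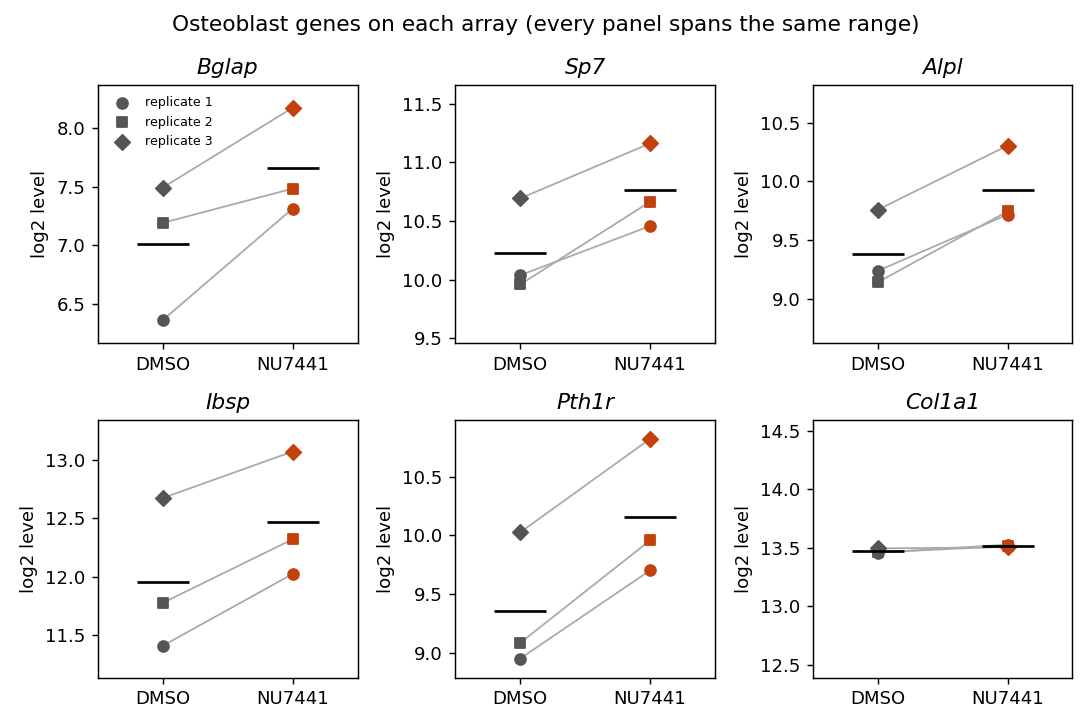
Log2 level of 6 genes of the osteoblast list on each array, with DMSO in grey and NU7441 in orange, a marker shape per replicate number, lines joining same-numbered samples and black bars at the group means (n = 3 each). In Bglap, Sp7, Alpl, Ibsp and Pth1r the line goes up for each number while the groups overlap. Col1a1 differs by 0.04 and lies near the arrays' maxima, where a rise may not show.

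Osteocyte genes were not called, with 11 of 17 higher (camera adjusted p = 0.266), among them Sost at 0.29 (SE 0.13), Fbln7 at 0.42 (SE 0.20) and Dmp1 at 0.14 (SE 0.61), with Pdpn at -0.18 (SE 0.09). In NU7441 1 to 3 Sost was at 6.33, 6.39 and 6.81 and Fbln7 at 8.03, 8.09 and 8.81. Most of both differences thus came from NU7441 3. With same-numbered samples as pairs the list was again not called (adjusted p = 0.0508, and adjusted p = 0.489 with pairs and an estimated correlation), and 1 member, Phex, at 0.97 (SE 0.58 without pairs and 0.10 with pairs), the largest difference of the list, passed adjusted over the list alone. Chondrocyte genes were called higher by camera, with 18 of 23 higher and a median of 0.19 (camera adjusted p = 6.59e-04, and adjusted p = 0.358 with an estimated correlation). The cartilage matrix gene Matn4 differed by 0.59 (SE 0.21), Ucma by 0.37 (SE 0.13), Snorc by 0.26 (SE 0.09) and Matn1 by 0.23 (SE 0.08), and 0 members passed adjusted over the list alone without pairs, and 1, Matn4, with same-numbered samples as pairs. Matn1 was at 4.99 in DMSO and 5.22 in NU7441, and Ucma at 5.30 and 5.67. Both lay near the arrays' lower quartiles of 5.11 to 5.16, so the sizes of their differences are uncertain. The chondrocyte list's median was 0.12 without DMSO 3 and 0.12 without NU7441 3. Genes of Wnt signalling were also called higher by camera, with 24 of 31 higher and a median of 0.08 (camera adjusted p = 0.00442, and adjusted p = 0.558 with an estimated correlation). Its examples were Tnfrsf19 at 0.59 (SE 0.12), the Wnt agonist Rspo2 at 0.29 (SE 0.08), the receptor Fzd8 at 0.28 (SE 0.08) and the Wnt inhibitor Nkd1 at 0.27 (SE 0.09), none passing over all genes or adjusted over the list alone without pairs. With pairs 2 members passed adjusted over the list alone, Tnfrsf19 and the inhibitor Wif1 at 0.95 (SE 0.42 without pairs and 0.08 with pairs), both higher. The Wnt median was 0.14 without DMSO 3 and 0.15 without NU7441 1, and the call was lost with DMSO 2 and NU7441 3 both left out (adjusted p = 0.301).

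Genes of hypoxia and glycolysis were called lower by camera: 25 of 27 measured members were lower and 2 higher, with a median of -0.23 (camera adjusted p = 2.42e-13). The adjusted p was 0.276 with an estimated correlation. Slc2a1, the glucose transporter GLUT1, differed by -0.44 (SE 0.07), Vegfa, the angiogenic growth factor, by -0.40 (SE 0.07), the oxygen sensor Egln1 by -0.42 (SE 0.08) and the phosphofructokinase Pfkp by -0.29 (SE 0.06). Over all genes 0 members passed in limma and 13 had an unadjusted p under 0.05, all lower. Adjusted over the list alone, 7 passed, all lower: these genes and Ndrg1, Pgam1 and Higd1a. With same-numbered samples as pairs, 13 passed adjusted over the list alone, again all lower.

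**Figure D2:**
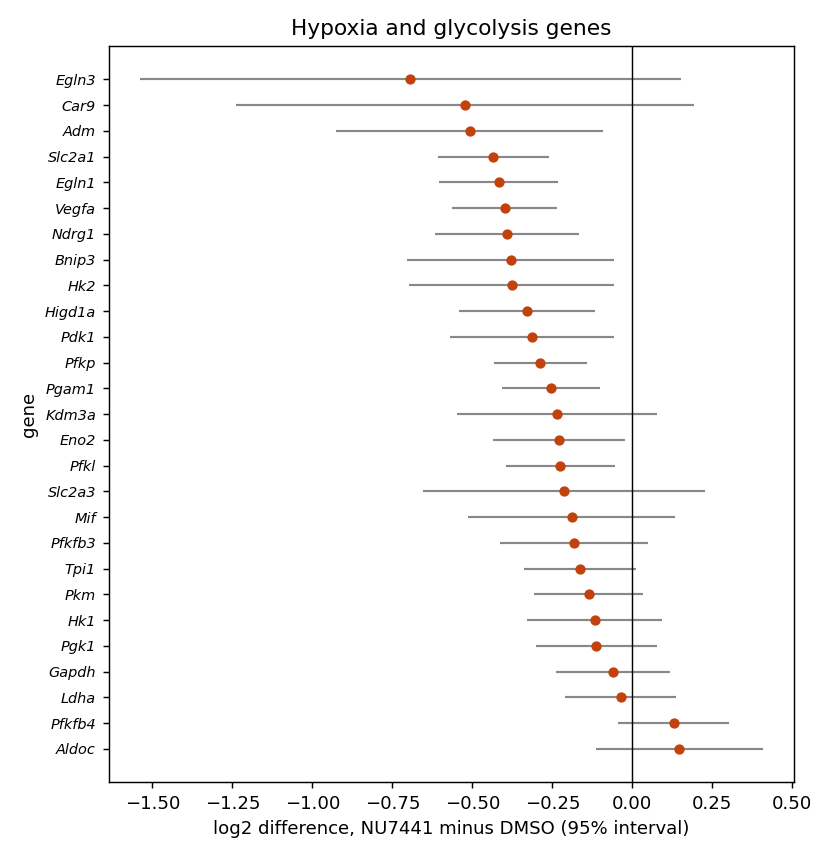
Log2 difference, NU7441 minus DMSO, of the 27 measured genes of the hypoxia and glycolysis list, with dots for the estimate and lines for the 95% interval from limma (n = 3 each). The dots of 25 genes lie below 0, and the median is -0.23.

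Inflammatory and NF-kB genes were called lower by camera, with 21 of 24 lower and a median of -0.11 (camera adjusted p = 2.61e-05, and adjusted p = 0.161 with an estimated correlation). The cytokine Il33 differed by -0.66 (SE 0.16), the chemokine Ccl2 by -0.56 (SE 0.14) and Nos2, the inducible nitric oxide synthase, by -0.34 (SE 0.08). These 3 passed adjusted over the list alone, of which Il33 and Ccl2 did so with pairs too, and 0 passed over all genes. Keeping only the upper 50 percent of genes by level ended the camera call (adjusted p = 0.0674).

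Genes of the amino acid and ATF4 response were called lower by camera, with 24 of 25 lower and a median of -0.24 (camera adjusted p = 1.47e-04), as were those of the unfolded protein response, with 17 of 18 lower and a median of -0.24 (camera adjusted p = 1.94e-04). Each had an adjusted p = 0.558 with an estimated correlation, and 0 members of either passed adjusted over the list alone, with pairs or without. Slc7a11, the cystine transporter, was at 6.94 ± 1.27 in DMSO and 5.97 ± 0.27 in NU7441, a difference of -0.97 (SE 0.57), and the stress factor Ddit3 differed by -0.68 (SE 0.39). Dnajb9 differed by -0.44 (SE 0.21) and Dnajb11, both co-chaperones of the endoplasmic reticulum, by -0.30 (SE 0.12). The arrays of a group differed widely in these lists. Against the genes' means over the 6 arrays, the ATF4 list's median was -0.29 in DMSO 1, 0.43 in DMSO 2 and 0.24 in DMSO 3, against -0.22, -0.08 and -0.09 in NU7441 1 to 3. The median of the members' differences within the pair numbered 1 was 0.14, higher with NU7441, and -0.47 and -0.34 in the pairs numbered 2 and 3. The unfolded protein list's median was 0.43 in DMSO 2 and between -0.19 and -0.05 in the other 5 arrays. Without DMSO 2 the medians of the differences were -0.08 and -0.01 and the camera adjusted p 0.189 and 0.452, and without DMSO 1 the ATF4 median was -0.45.

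Lysosome and autophagy genes were called lower by camera, with 24 of 25 lower and a median of -0.08 (camera adjusted p = 2.26e-04, and adjusted p = 0.558 with an estimated correlation). Genes of mitochondrial oxidative phosphorylation were called lower too, with 22 of 32 lower and a median of -0.06 (camera adjusted p = 0.00713, and adjusted p = 0.558 with an estimated correlation). Genes of cytosolic ribosomal proteins were called higher by camera, with 27 of 33 higher and a median of 0.07 (camera adjusted p = 6.59e-04, and adjusted p = 0.558 with an estimated correlation). In all 3 lists 0 members passed adjusted over the list alone, with pairs or without. Examples were the proton pump subunit Atp6v1h at -0.19 (SE 0.08), Tfam, a mitochondrial transcription factor, at -0.19 (SE 0.07), and Rplp1 at 0.21 (SE 0.07). The oxidative phosphorylation call was lost without DMSO 2 (adjusted p = 0.113), with quantile normalization (0.108) and in the upper 50 percent of genes by level (0.0898), and the ribosomal call without DMSO 1 (0.0781). The lysosome call was lost with DMSO 2 and NU7441 3 both left out (0.275), and the medians of the oxidative phosphorylation and ribosomal lists moved to -0.04 and 0.11 without DMSO 2, the ribosomal one to 0.04 without DMSO 1.

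The other lists were not called by camera. Cell cycle genes had 33 of 38 higher, with a median of 0.10 (adjusted p = 0.0858), and were called higher with same-numbered samples as pairs (adjusted p = 2.45e-04, and adjusted p = 0.571 with pairs and an estimated correlation). They were also called higher without DMSO 1 (0.00453), DMSO 3 (3.16e-04) or NU7441 2 (1.02e-05), with an intensity trend and robust prior (0.0410), with quantile normalization (0.0256), with median centring (0.0365) and in the upper 75 (0.0383) or 50 percent (0.00414) of genes by level. They were called lower without DMSO 2 (0.0177) and with DMSO 2 and NU7441 3 both left out (3.50e-11). Against the genes' means over the 6 arrays, their median was -0.44 in DMSO 2 and between -0.21 and 0.30 in the other arrays. AP-1 and immediate early genes had 17 of 22 lower (0.0858), called lower with pairs (adjusted p = 0.0499, and adjusted p = 0.571 with pairs and an estimated correlation), and Jun passed adjusted over the list alone. They were called lower without DMSO 1 (0.0304), DMSO 2 (0.0189) or NU7441 1 (0.00279) too. Genes of xenobiotic and oxidative stress had 16 of 23 lower (0.125), called lower with pairs (adjusted p = 0.0263, and adjusted p = 0.489 with pairs and an estimated correlation), without DMSO 3 (0.0270) and without NU7441 2 (0.0224), with Hmox1 at -0.67 (SE 0.26). The adjusted p was 0.266 for interferon response, with Ccl5 at 0.69 (SE 0.15), for BMP and TGF-beta signalling, with Id3 at 0.58 (SE 0.17), for collagen and matrix assembly and for adipocyte genes. Interferon genes were called higher without DMSO 2 (1.25e-05), without NU7441 3 (0.00300) with array weights (0.00379) and with DMSO 2 and NU7441 3 both left out (3.87e-10), but lower without DMSO 3 (0.0264), and the BMP list was called higher without DMSO 3 (0.0270). Grem1 in the BMP list and Fabp4, a fatty acid binding protein at -0.99 (SE 0.19), in the adipocyte list passed adjusted over the list alone. Fabp4 was at 5.87 in DMSO and 4.87 in NU7441, the latter below every array's lower quartile, 5.11 to 5.16, so the size of its difference is uncertain. The matrix list held members in both directions, Thbs1 at 0.33 (SE 0.07) and Lum at -0.85 (SE 0.20), and fry's test of change in either direction gave it an adjusted p of 0.0128. That test called 4 of the 26 lists, the others being hypoxia and glycolysis (0.0128), inflammatory (0.0132) and oxidative phosphorylation (0.0395), where fry's test of a shared direction called 0. With pairs, 7 members of the BMP list, 6 of the matrix list, Fabp4 and Hmox1 passed adjusted over their list alone, and Jun did not. Matrix proteases and inhibitors had an adjusted p of 0.331 in camera, with Timp3 at -0.53 (SE 0.14), and sterol biosynthesis 0.676, with a call lower without DMSO 2 (0.00911).

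Of the genes that repair DNA or respond to its damage, those of non-homologous end joining, the pathway of the inhibited kinase, had 10 of 16 lower (camera adjusted p = 0.453), with Xrcc5 at -0.18 (SE 0.09). Genes of homologous recombination and damage signalling had 12 of 22 higher (0.803), and p53 targets 14 of 28 higher (0.736). Among p53 targets Tnfrsf10b was at -0.20 (SE 0.07), Ddit4l at 0.24 (SE 0.09) and Trp53inp1 at 0.18 (SE 0.08). Markers of muscle, macrophage and endothelial cells were not called either. The camera adjusted p was 0.258 for macrophage and endothelial genes, 0.580 for smooth muscle and myofibroblast genes and 0.923 for skeletal muscle genes.

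**Figure D3:**
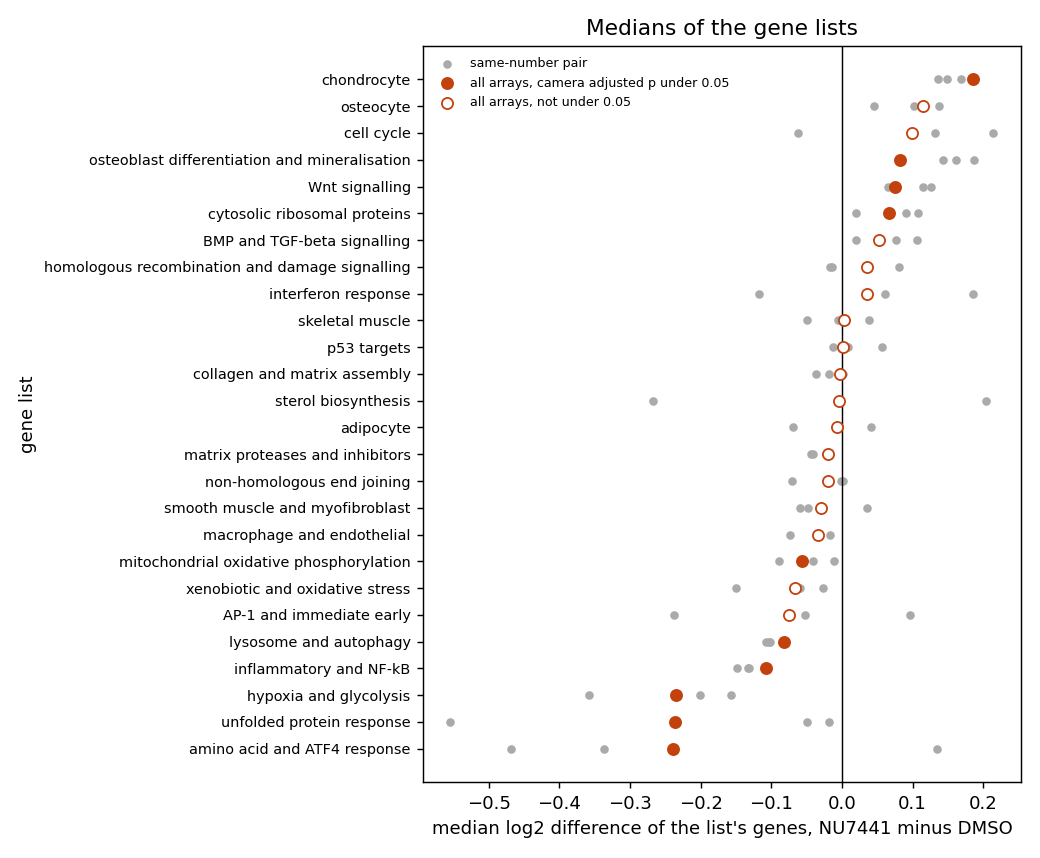
Median log2 difference, NU7441 minus DMSO, of the genes of each of the 26 lists, with large dots for all arrays (filled where the camera adjusted p was under 0.05) and small grey dots for each same-numbered pair. The filled dots are 4 lists to the right of 0 and 6 to the left.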

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

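The settings that join pairs to a trend or a filter, those that join pairs to other list tests, and the one with 4 arrays were chosen after the data were examined, and the last 2 of the paired gene settings after the first had given its count. Of 19 settings for single genes, the 15 planned ones called 0 genes in limma, and 3 of the 4 added ones called some. Pairs (replicate block) with an intensity trend and a robust prior called 100 genes, 7 of them by 2-fold; without the robust prior it was the same 100 genes, 7 by 2-fold; and pairs in the upper 50 percent of genes by level called 44, 5 by 2-fold, 43 of them among the 100. The replicate block alone called 0 genes and 13 lists where the test without it called 10, and apart from the cell cycle, xenobiotic and AP-1 lists it changed no other call. The camera calls became 0 lists with an estimated correlation, 0 with fry, 0 with the replicate block and an estimated correlation, and 1, the osteoblast list, with the replicate block and fry. In these settings the adjusted p of the hypoxia list was 0.276, 0.0831, 0.434 and 0.137, and that of the osteoblast list 0.558, 0.587, 0.341 and 0.0413. The inflammatory call was lost too at its estimated correlation of -0.008, below the preset 0.01. Losses at estimated correlations thus do not measure correlation between genes alone. Leaving out each array gave the hypoxia list an adjusted p between 2.33e-15 and 4.88e-08, and the osteoblast list one between 5.14e-04 and 0.154. The osteoblast call was also lost with array weights (0.0539) and with 4 arrays, DMSO 2 and NU7441 3 left out (0.492), which also ended the Wnt (0.301), lysosome, oxidative phosphorylation and ATF4 (0.275 each) and unfolded protein (0.477) calls. Over all settings, list calls were lost in 56 tests of 520 and gained in 22. Directions turned for cell cycle genes, lower without DMSO 2 (0.0177; from 1.02e-05, a call higher, to 0.590 over the arrays left out) and with 4 arrays (3.50e-11), for interferon genes, lower without DMSO 3 (0.0264; from 1.25e-05, a call higher, to 0.912), and for homologous recombination genes, lower with 4 arrays (0.0266). The cause of these changes was not tested. Among 2264 values of named genes, 15, from 10 genes, had another sign, none of them past the threshold. Dropping genes shared between lists moved nothing, since none was shared. Signal over background was not analysed here.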

Other observations

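The tests of a single array, of brightness and of the pairing, the splits for counts of 0, the swaps within pairs, and the list settings with pairs were chosen only after the result was seen. The genes of the next paragraph, and Slc16a3, Pfkfb4, Aldoc and Ldha, were also chosen after their values were seen.

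With same-numbered samples as pairs, an intensity trend and a robust prior, limma called 100 genes, 39 higher and 61 lower with NU7441. Sizes ranged from 1.17-fold to 2.26-fold, with a median of 1.44-fold. Higher were Panx3, a channel protein of bone and cartilage, by 1.16 on the log2 scale (adjusted p = 0.00262), Smpd3, a sphingomyelinase needed for mineralisation, by 1.14 (0.00262), Phex, an endopeptidase of osteocytes and osteoblasts mutated in hypophosphataemic rickets, by 0.97 (0.00807), and Ifitm5, a membrane protein of osteoblasts, by 0.94 (0.0117). The Wnt inhibitor Wif1 was higher by 0.95 (0.00404) and Car3, a carbonic anhydrase, by 1.09 (0.00466). Lower were Atp1b1, a sodium pump subunit, at -1.13 (0.00404), Ero1a, an oxidase of the endoplasmic reticulum, at -0.64 (0.00467), and Serpina3n at -0.83 (0.0160). Of the 24 osteoblast genes 6 were among the 100, all higher, where 0.108 would fall by chance if genes were independent, and of the 27 hypoxia and glycolysis genes 5, all lower, where 0.122 would. The 100 also held 4 of 30 genes of BMP and TGF-beta signalling, 2 higher and 2 lower, where 0.135 would, and 3 of 38 collagen and matrix genes, 1 higher and 2 lower, where 0.171 would. Inflammatory genes gave 2, both lower, and Wnt genes 2, both higher. Genes of a list are not independent, the correlation estimated without pairs being 0.156 in the osteoblast and 0.177 in the hypoxia list. Such genes can be called together, so the counts expected by chance do not measure how unusual the observed ones are. This setting was added after the data were examined, and the 15 planned ones called 0 genes.

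Of the 10 splits of the 6 arrays into 3 and 3, all 10 gave as many genes past the adjusted threshold as the real split, 0, and all 10 as many at 2-fold, 0, the highest other being 0. For genes at an unadjusted p under 0.05, 2 of 10 splits gave as many, with 1506 in the real split and 1715 in the highest other, which set DMSO 1, DMSO 2 and NU7441 1 against the rest, and for lists called by camera 3 of 10 did, with 10 and 11 lists. The splits that exceeded the real one part 1 pair, and among the 4 that part all 3 pairs the highest other gave 951 genes and 5 lists. Of these 4, 1 gave as many genes with pairs, trend and robust prior, the real one with 100, and the highest other gave 0. Neither 10 nor 4 splits can give a share under 0.05.

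The lower hypoxia and glycolysis genes may reflect lower activity of hypoxia-inducible transcription factors, a hypothesis formed on these data. Not all members of the list fell: Pfkfb4 was higher at 0.13 (SE 0.07) and Aldoc at 0.15 (SE 0.11). Ldha differed by -0.04 (SE 0.07). A list of 30 other targets, written after the hypoxia result but before their values were seen, had a median log2 difference of -0.10, at percentile 0.01 of 10000 random lists matched on level, with 21 lower and 9 higher. Their camera p was 3.49e-04 and 0.0945 with an estimated correlation, 0 passed adjusted over the list alone, and Slc16a3, a lactate transporter, went the other way at 0.23. Random lists lack genes that move together, so the percentile does not measure how often such targets would shift by chance. The targets were read on the same 6 arrays as the first list, so a difference between dishes could move both. A single array as the cause is argued against by the highest median with 1 array left out, -0.22, with the camera call kept in 6 of 6 such tests, and a shift of genes of like brightness by a percentile of 0 for the first list. Of the 10 splits, too few for a share under 0.05, 1 gave as large a mean statistic, 2.41 in the real split against 1.11 in the highest other, and culture density or oxygen supply, which could differ between dishes, was not tested.

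In the osteoblast list, 13 of 24 genes were higher with NU7441 in all 3 same-numbered pairs and 1 was lower in all 3, and the medians of the pairs were 0.14, 0.16 and 0.19. The median stood at percentile 100 of random lists matched on level, which argues against a shift of like-bright genes as the whole cause. A single array stays open: the lowest median with 1 array left out was 0.0628, at percentile 99.97 of random lists on the same 5 arrays, but the camera call was lost in 3 of 6 such tests. With pairs, 1 of the 4 splits that part all 3 pairs gave as large a mean statistic, 3.09 in the real split and 0.44 in the highest other, without pairs 3 of 10 did, with 0.81 and 1.41, and the labelled pairing ranked 1 of 6 by the spread of pair differences, with a median SD of 0.144 against 0.170 in the next, where neither 4 nor 10 splits nor 6 pairings can give a share under 0.05. No biological explanation was tested, and the osteocyte list was not called (camera adjusted p = 0.266, and 0.0508 with pairs). Col1a1 differed by 0.04, but it was at 13.47 in DMSO, near the arrays' maxima of 13.94 to 13.96, where a rise may not show.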
